A study of Homo sapiens with 106 samples.

How the data were processed

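Total RNA of MCF-7 cells, a human breast cancer line, was measured on HG-U133 Plus 2 arrays in 12 groups, 10 arrays in each of 10 groups and 3 in each of the 2 lasofoxifene groups. E2 was given at 1 nM and the other ligands at 100 nM for 24 h, beginning 48 h after plating. The treatment protocol names DMSO as the vehicle of the ligands while the sample characteristics name ethanol, and the labels do not settle which was used. The deposited values are log2 expression per probe set, made by the authors with GCRMA, whose version is not given. The quartiles of all arrays lie within 0.017 log2 units of each other, as after quantile normalization, and no value is missing. Values ran from 0.858 to 15.546, their 5th percentile was 2.154, and no detection calls were given, so a value near the floor cannot be told from background. Raw intensities were not analysed here.

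Of 54675 probe sets, 41097 carried exactly 1 gene symbol, 1801 several and 11777 none in the annotation used. For each of 19775 symbols the probe set with the highest mean over all arrays was taken, and a gene was tested where its highest group mean was at least 4, which left 10307. CYP1A1 stayed below this floor, and LDLR was not named in the annotation and is not analysed here. Genomic positions are not given.

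The groups came from the labels. A one-way limma model over all arrays gave 41 contrasts: E2 against vehicle, each ligand against vehicle, each ligand with E2 against E2 alone and against the ligand alone, the interaction of E2 with each ligand, and all pairs of ligands without and with E2. Moderated statistics (eBayes) were adjusted by the Benjamini-Hochberg method within each contrast over the genes tested. A gene was called at an adjusted p under 0.05, and a second count took called genes of at least 2-fold. Gene lists written before the data were examined were tested with camera at a preset correlation of 0.01, adjusted over 738 tests, 216 of which were called. With an estimated correlation 48 were called, all among the 216. The lists were estrogen-induced and estrogen-repressed genes, G1/S and DNA replication, G2/M and mitosis, cholesterol and fatty acid synthesis, aryl hydrocarbon receptor targets, the unfolded protein response, lysosome, interferon response, BCL2 family, luminal identity, basal and mesenchymal genes, hypoxia and glycolysis, growth factor receptors, estrogen receptor cofactors, immediate early and stress genes, ribosomal proteins, and markers of fibroblasts and of leukocytes and endothelium.

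List scores, the mean log2 value of a list per array, were compared between ligands by 2-sided permutation tests with 100000 resamples, whose smallest p is 1e-05, or by exact permutation where a group held 3 arrays, whose smallest p is 0.00699. The 140 tests were adjusted together, and 95% intervals came from a one-way fit. The share of the E2 response left is the slope through 0 of the E2 effect with the ligand on that without it, and the share given is the slope of the ligand effect on the E2 effect with the vehicle arrays divided between both. Intervals came from 1000 resamples of arrays within groups.

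The rule for named genes was fixed before the data were examined: a set of 20 known genes, the largest rises and falls among called genes of each contrast (8 and 8 for E2, 4 and 4 for the ligands, 2 and 2 for pairs and interactions), and up to 4 list members with the largest change. Genes named outside this rule are marked as such. The title numbers form 10 sets of 15, each with 1 array of 10 groups, and these numbering sets served as an alternative block. The array medians form 2 parts, 2.644 in sets 7 to 10 and in the third array of both lasofoxifene groups, and 2.647 to 2.652 in the other arrays. The labels do not pair the lasofoxifene arrays, but arrays of the same order in LAS and E2+LAS deviated together (r = 0.366, 0.397 and 0.363), while those of different order had r from -0.256 to -0.0909. Recovery of known changes was tested on simulated data for 10 arrays against 10, 3 against 10 and 3 against 3. Of genes changed 1.2-fold, 80%, 38% and 34% were recovered. At 1.5-fold it was 98%, 86% and 84%, and at 2-fold 100%, 100% and 98%. Counts of called genes with 3 arrays in a group are therefore not comparable with those of 10 against 10. The simulated noise was independent between genes and held no set effects. The larger changes in the same simulation also eased the threshold for the small ones. Recovery on the real arrays may therefore be lower.

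The alternatives were quantile normalization, median centring, no floor or a floor of 6, the mean of all probe sets of a gene, every probe set counted alone, the numbering set as a block, the arrays of the compared groups alone, array weights, a trended and robust fit, and leaving out 6 arrays whose label carried an extra suffix. Under alternatives the numbers of called genes are given in part as percent of the features tested. For contrasts of lasofoxifene each of its arrays was left out in turn. For lists the alternatives were an estimated correlation, the block and quantile normalization, and for list scores quantile normalization and median centring. For shares they were genes of at least 1.5-fold, the estrogen-induced list, no floor, and another division of the vehicle arrays. After the data were examined 6 alternatives were added: leaving out the 3 arrays that correlated least with their group, the set as a random block in every contrast, leaving out lasofoxifene arrays in list scores and shares, the 2 parts by array median as a term, the lasofoxifene arrays paired by order without and with the sets as terms, and list scores compared within sets. The last used exact sign flips, whose smallest p is 0.00195, and kept the unpaired p for pairs with LAS. Scores were also compared between the 2 parts by array median over all 210 splits of the 10 sets into 6 and 4. For contrasts of lasofoxifene with other groups the block could only be fitted as random. In that fit the arrays of both lasofoxifene groups shared a block, although they deviated together by order. Lower counts under it may reflect this assignment. R 4.3.3, limma 3.58.1, jsonlite 2.0.0 and version 1.17.8 of data.table were used with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.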

Results

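Gene expression was measured in MCF-7 cells, an estrogen receptor positive human breast cancer cell line, with oligonucleotide arrays of 54675 probe sets. The cells had been plated for 48 h and were then treated for 24 h. The 12 groups were vehicle, 1 nM estradiol (E2), and 5 estrogen receptor ligands at 100 nM, each without and with 1 nM E2. The ligands were 4-hydroxytamoxifen (4OHT), fulvestrant (ICI), bazedoxifene (BZA), raloxifene (RAL) and lasofoxifene (LAS). Each group held 10 arrays, except that LAS and E2+LAS held 3 each. The lasofoxifene arrays carried their own run of title numbers, so comparisons of them with other groups may also be comparisons between runs, apart from E2+LAS against LAS. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical in part. The deposited values were log2 expression values between 0.858 and 15.546 with a median of 2.647, and the number of arrays limits their precision. Of 19775 named genes, 10307 were tested in each of 41 comparisons, and ± gives the SE of the limma fit unless another error is named. A mean below 4 may lie at the background, so a difference with such a mean on one side may be a lower bound in size.

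The comparison of E2 with vehicle asks what the natural agonist does in these cells. E2 raised EGR3, a zinc finger transcription factor, from a mean of 3.03 to 7.76, a log2 difference of 4.74 ± 0.14 (n = 10 per group, adjusted p = 9.91e-54). It raised MYBL1, a MYB family transcription factor, by 4.58 ± 0.22, although the other probe set of MYBL1 rose by 0.22. CDH26, a cadherin, rose by 4.23 ± 0.17, and GINS4, a subunit of the GINS complex of the DNA replication fork, by 4.02 ± 0.15. RAMP3, PDZK1, RBM24 and the DNA glycosylase gene NEIL3 rose by 3.78, 3.77, 3.49 and 3.42. The largest falls were those of AHRR, the repressor of the aryl hydrocarbon receptor, from 8.12 to 3.81 (-4.30 ± 0.24), and of the interleukin receptor gene IL1R1, from 5.82 to 2.09 (-3.73 ± 0.14). WNT2B, the membrane peptidase gene MME, the cell cycle kinase gene CDK6, ASB9, the receptor tyrosine kinase gene ERBB4 and the dopamine receptor gene DRD1 fell by 3.31, 3.30, 3.08, 2.95, 2.94 and 2.69. The other probe set of MME fell by 1.09 and that of ERBB4 by 0.54. Each of these 16 genes moved the same way in 10 of 10 numbering sets. In all, 3524 genes rose and 3947 fell, of which 567 rose and 401 fell at least 2-fold. Means of EGR3, GINS4, RAMP3 and PDZK1 with vehicle and of AHRR, IL1R1, MME, ERBB4 and DRD1 with E2 lay below 4. They may lie at the background, so these differences may be lower bounds.

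Of 42 tested genes of a fixed list of known estrogen-induced genes, E2 raised 36 and lowered 2, both over all genes and adjusted over the list alone (camera adjusted p = 2.22e-17, and adjusted p = 0.018 with an estimated correlation). PGR, the progesterone receptor gene, rose by 3.20 ± 0.15, GREB1, an estrogen receptor cofactor, by 2.07 ± 0.14, the chemokine gene CXCL12 by 2.41 ± 0.15 and the trefoil factor gene TFF1 by 1.72 ± 0.12. The 2 members that fell were MYC (-0.38 ± 0.04) and STC2 (-0.49 ± 0.10), of which STC2 is named after its value was seen. Of 23 genes of the estrogen-repressed list 21 fell and none rose (adjusted p = 9.28e-11, and adjusted p = 0.0232 with an estimated correlation), among them BIK, a proapoptotic BCL2 family gene (-2.45 ± 0.12), TP53INP1 (-2.36 ± 0.07) and the receptor tyrosine kinase gene ERBB2 (-1.36 ± 0.08). ESR1, the estrogen receptor alpha gene, fell by 0.38 ± 0.06, while its 5 other probe sets stood at -0.33 to -0.04 and only 1 of them was called.

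Cell cycle genes rose together with E2. Of 36 genes of G1/S and DNA replication 35 rose, with a median log2 difference of 1.83 (adjusted p = 3.24e-20, and adjusted p = 0.14 with an estimated correlation), for example ORC1 (2.87 ± 0.13), CDC45 (2.81 ± 0.18) and MCM2 (1.58 ± 0.11). All 33 genes of G2/M and mitosis rose, with a median of 2.12 (adjusted p = 6.49e-16, and adjusted p = 0.321 with an estimated correlation), for example CENPE (2.62 ± 0.22), the proliferation marker MKI67 (2.40 ± 0.17) and CCNB1 (1.68 ± 0.12). Of 19 cholesterol synthesis genes 13 rose and 2 fell, and 15 rose and 2 fell adjusted over the list alone (adjusted p = 0.000656, and adjusted p = 0.2 with an estimated correlation). ACAT2, EBP and STARD4 rose by 1.46 ± 0.09, 1.12 ± 0.08 and 1.05 ± 0.11. Of 17 lysosomal genes 13 fell and 3 rose (adjusted p = 0.0134, and adjusted p = 0.449 with an estimated correlation). ASAH1 fell by 1.00 ± 0.05, while CTSD and GLA, which encode cathepsin D and alpha-galactosidase A, rose by 2.07 ± 0.10 and 2.02 ± 0.09.

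Other lists split between rises and falls or missed the threshold. All 15 called genes of 17 in the interferon response list fell (adjusted p = 0.0508), for example IFI44L (-2.16 ± 0.34) and MX1 (-1.44 ± 0.24). Of 14 growth factor receptor genes 8 fell and 1 rose (adjusted p = 0.0603), with RET up by 2.03 ± 0.10. Of 22 genes of the unfolded protein response 11 rose and 9 fell (adjusted p = 0.707), and of 14 luminal genes 3 rose and 8 fell (adjusted p = 0.254), with XBP1 up by 1.42 ± 0.10 and SPDEF down by 1.60 ± 0.07. Of 7 aryl hydrocarbon receptor targets 3 rose and 2 fell, for example TIPARP (1.08 ± 0.05) and NQO1 (-0.93 ± 0.05), and the median (-0.04) and mean (-0.29) differed in sign from the test (adjusted p = 0.825). Of 13 BCL2 family genes 4 rose and 7 fell (adjusted p = 0.342), with PMAIP1 up by 1.76 ± 0.14 and BMF down by 2.12 ± 0.14. BCL2 itself stood at 0.14 ± 0.08 and was not called. Of 11 fibroblast marker genes 2 were expressed highly enough to be tested, COL1A1 (0.09 ± 0.10) and COL5A1 (-0.55 ± 0.14), and of 11 leukocyte and endothelial marker genes none was. The immediate early and stress genes, which can move with handling, had a mean score of 8.577 with E2 and 9.039 with vehicle (permutation p = 1e-05 over groups, the smallest the resamples can give), and it also differed between numbering sets (8.639 to 9.106, permutation p = 1e-05). EGR1 fell by 1.80 ± 0.20.

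**Figure D1:**
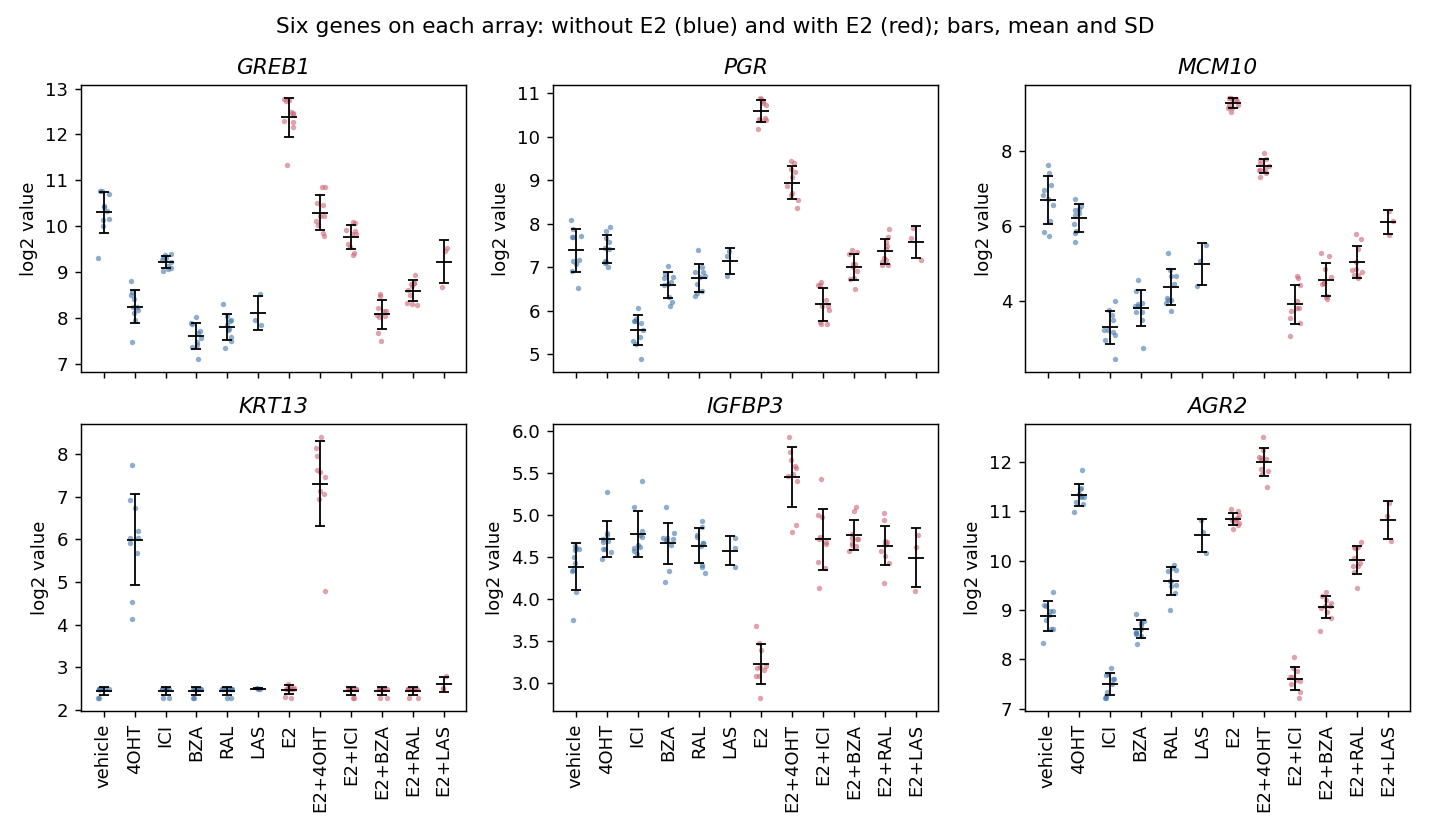
Log2 expression (y axis) of GREB1, PGR, MCM10, KRT13, IGFBP3 and AGR2 in each array (points) by group (x axis), with the group mean and SD. KRT13 stands at a mean of 5.99 with 4OHT and 7.31 with E2+4OHT against 2.45 with vehicle, and MCM10 at 9.28 with E2 against 3.30 with ICI.

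4OHT alone, the active metabolite of tamoxifen, was compared with vehicle to see what it does without an agonist. It raised the long noncoding RNA LINC01588 from 2.52 to 7.72 (5.20 ± 0.17, adjusted p = 2.82e-47), the keratin gene KRT13 from 2.45 to 5.99 (3.55 ± 0.20), the chloride channel gene CLIC3 from 7.14 to 10.50 (3.36 ± 0.10) and the adhesion molecule gene SDK2 from 2.92 to 6.15 (3.23 ± 0.11), each in 10 of 10 numbering sets. The vehicle means of LINC01588, KRT13 and SDK2 lie near the background, so their differences may be lower bounds. GREB1 fell from 10.30 to 8.24 (-2.05 ± 0.14), although its other probe set stood at -0.38 and was not called. RFTN1, the monoamine oxidase gene MAOB and the calcium pump gene ATP2C2 fell by 1.76 ± 0.11, 1.45 ± 0.15 and 1.31 ± 0.11. The estrogen-induced list split: 17 of 42 genes rose and 10 fell, and 19 rose and 13 fell adjusted over the list alone (adjusted p = 7.6e-08, and adjusted p = 0.195 with an estimated correlation). KRT13, the protease inhibitor gene SERPINA1 (2.47 ± 0.15) and the receptor gene RET (1.97 ± 0.10) rose, and GREB1, CXCL12 (-0.95 ± 0.15) and TFF1 (-0.61 ± 0.12) fell. PGR stood at 0.04 ± 0.15 and was not called.

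Few cell cycle genes were called with 4OHT alone. Of 36 G1/S genes, SLBP rose (0.16 ± 0.06, named after its value was seen) and GINS3 fell (-0.32 ± 0.11), and none was called adjusted over the list alone. The list as a whole stood lower (median -0.15, adjusted p = 0.0156, and adjusted p = 0.89 with an estimated correlation). None of the 33 mitotic genes was called, and the median was -0.04. These averages pool 2 parts of the arrays, told apart by their array medians, that differed in a test chosen after the data were seen. The G1/S score minus vehicle was -0.324 in sets 1 to 6 and 0.082 in sets 7 to 10 (exact permutation p = 0.0143, adjusted p = 0.0455), and the mitosis score -0.185 and 0.185 (exact permutation p = 0.019, adjusted p = 0.0476). A shift of the vehicle arrays between the parts may contribute to both. Of 9 fatty acid synthesis genes 2 rose, and 3 adjusted over the list alone (adjusted p = 0.0147, and adjusted p = 0.458 with an estimated correlation), among them ELOVL6 (0.26 ± 0.07). In all, 650 genes rose and 616 fell, 50 and 11 of them at least 2-fold. With the numbering set as a block 2132 genes were called in place of 1266.

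ICI, BZA and RAL alone lowered cell cycle genes below vehicle. MCM10, a replication initiation factor gene, fell from 6.69 to 3.30 with ICI (-3.40 ± 0.19, adjusted p = 7.35e-29), to 3.80 with BZA (-2.89 ± 0.19) and to 4.37 with RAL (-2.33 ± 0.19), in 10 of 10 sets each. The means with ICI and BZA lie below the floor of 4, so those falls may be lower bounds. The 2 other probe sets of MCM10 were also called but fell less. They stood at -1.64 and -1.26 with ICI, -1.51 and -1.24 with BZA, and -1.29 and -0.73 with RAL. DTL fell by 3.04 ± 0.20, 2.45 ± 0.20 and 1.85 ± 0.20 in the same order. Of 36 G1/S genes 33 fell with ICI (median -1.27), 32 with BZA (median -1.04) and 33 with RAL (median -0.91), and none rose. These 3 calls held with an estimated correlation at adjusted p = 0.00158, 0.000535 and 0.00218. Of 33 mitotic genes 33, 32 and 32 fell, with medians of -1.17, -0.79 and -0.71 (adjusted p = 6.77e-31, 1.23e-28 and 6.9e-20, and adjusted p = 0.104, 0.128 and 0.235 with an estimated correlation).

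The estrogen-induced list fell most plainly with ICI: 32 of 42 genes fell and none rose, and 34 fell adjusted over the list alone (adjusted p = 4.48e-33, and adjusted p = 0.000585 with an estimated correlation). MYBL1, CXCL12 and PGR fell by 2.93 ± 0.22, 2.01 ± 0.15 and 1.84 ± 0.15, although the other probe sets of MYBL1 and PGR were not called. The mean of MYBL1 with ICI lay below 4, so its fall may be a lower bound. With BZA 21 fell and 7 rose, and 22 fell and 7 rose adjusted over the list alone (adjusted p = 2.42e-12, and adjusted p = 0.0711 with an estimated correlation), and with RAL 14 fell and 9 rose, and 17 fell and 9 rose adjusted over the list alone (adjusted p = 0.0245, and adjusted p = 0.732 with an estimated correlation). GREB1 fell by 2.69 ± 0.14 with BZA and by 2.50 ± 0.14 with RAL, while its other probe set stood at -0.39 with each and was not called. ZNF367 fell by 2.18 ± 0.18 with BZA. Of 23 estrogen-repressed genes 15 rose with ICI (adjusted p = 1.33e-07, and adjusted p = 0.0899 with an estimated correlation), for example IL1R1 (1.13 ± 0.14) and PSCA (1.01 ± 0.12). Of 19 cholesterol synthesis genes 11, 7 and 6 fell with ICI, BZA and RAL, and 12, 8 and 7 adjusted over the list alone (adjusted p = 9.18e-05, 0.00309 and 0.0054, and adjusted p = 0.14, 0.277 and 0.321 with an estimated correlation). Of 17 lysosomal genes 8 rose and 1 fell with ICI (adjusted p = 0.0491, and adjusted p = 0.606 with an estimated correlation).

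Other genes that rose with these ligands were PPFIBP2 (1.15 ± 0.13) and AHRR (0.96 ± 0.24) with ICI, and PLEKHM3, ASB9 and ANXA9 (0.69, 0.67 and 0.62) with BZA. With RAL, ARHGEF28 rose by 1.07 ± 0.12, the sodium channel gene SCNN1A by 0.87 ± 0.25 (0.08 and not called with its other probe set), the kinase gene LYN by 0.82 ± 0.14 and the glucose transporter gene SLC2A1 by 0.79 ± 0.07. ICI raised 1261 genes and lowered 1462, 3 and 157 of them at least 2-fold. BZA raised 556 and lowered 898, and RAL raised 750 and lowered 1010. With the numbering set as a block the called genes numbered 2418 with BZA in place of 1454, and 2736 with RAL in place of 1760, and with the arrays of the compared groups alone they fell to 928 and 967.

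LAS alone also lowered GREB1 (-2.19 ± 0.21), MYBL1 (-1.88 ± 0.32), MCM10 (-1.71 ± 0.28) and MAOB (-1.63 ± 0.22) against vehicle, and raised ARHGEF28 (1.74 ± 0.18), the disulfide isomerase gene AGR2 (1.64 ± 0.16, from 8.88 to 10.52), SDK2 (1.36 ± 0.17) and TMEM120B (1.35 ± 0.18). Of 36 G1/S genes 24 fell, and 28 adjusted over the list alone (adjusted p = 2.84e-23, and adjusted p = 0.0982 with an estimated correlation). None of the 33 mitotic genes was called, though the list stood lower (median -0.21, adjusted p = 0.00963, and adjusted p = 0.897 with an estimated correlation). Of 42 estrogen-induced genes 9 rose and 9 fell. The other probe sets of GREB1, MYBL1 and TMEM120B, at -0.34, 0.19 and 0.48, were not called. Those of MCM10 stood at -0.895 and -0.305, and only 1 of them was called. The means of MYBL1 with LAS and of SDK2 with vehicle lay below 4, so these differences may be lower bounds. In all, 305 genes rose and 338 fell. The count was 400 without LAS replicate 1, 379 without LAS replicate 2, 293 with the set as a block and 1030 with no filter. The block took the arrays of both lasofoxifene groups as the same set. With the arrays of the compared groups alone 1.47% of the tested genes were called in place of 6.24%, and any effect of a separate run of the LAS arrays cannot be separated from the ligand here.

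In the presence of E2 each ligand moved most E2 genes back, which addresses how far each compound opposes the agonist. MYBL1 was lower than with E2 alone by 6.26 ± 0.22 with ICI, 6.20 ± 0.22 with BZA, 5.98 ± 0.22 with RAL, 5.44 ± 0.32 with LAS and 4.19 ± 0.22 with 4OHT (the last from 10.08 to 5.89). Its other probe set stood at -0.04 with ICI and was called with LAS only. EGR3 differed from E2 alone by -4.49 ± 0.14 with 4OHT, -4.94 ± 0.14 with ICI, -5.04 ± 0.14 with BZA, -4.95 ± 0.14 with RAL and -4.89 ± 0.20 with LAS. AHRR was higher by 4.67 ± 0.24 with ICI, 4.04 ± 0.24 with BZA, 3.81 ± 0.24 with RAL and 3.59 ± 0.36 with LAS, and IL1R1 by 4.46 ± 0.14, 4.05 ± 0.14, 3.83 ± 0.14 and 3.52 ± 0.21. These differences of EGR3, AHRR and IL1R1 have a mean below 4 on one side and may be lower bounds. The same holds for MYBL1 with ICI and with BZA. Of 42 estrogen-induced genes 26 fell and 10 rose with 4OHT, 40 and 1 with ICI, 37 and 1 with BZA, 34 and 2 with RAL, and 33 and 3 with LAS. The adjusted p was 4.01e-05, 3.08e-19, 2.74e-17, 1.61e-13 and 6.5e-12, and with an estimated correlation the adjusted p = 0.372, 0.0118, 0.018, 0.0527 and 0.0769.

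All 33 mitotic genes were lower than with E2 alone for each of the 5 ligands, with medians of -1.58 (4OHT), -3.02 (ICI), -2.72 (BZA), -2.60 (RAL) and -1.97 (LAS), and with an estimated correlation the adjusted p = 0.348, 0.25, 0.25, 0.251 and 0.326. Of the G1/S genes 35 of 36 fell with 4OHT, ICI, BZA and RAL and 36 with LAS, with an estimated correlation at adjusted p = 0.183, 0.0772, 0.0682, 0.0711 and 0.0682. Of 17 lysosomal genes 14 rose with 4OHT, ICI, BZA and RAL and 13 with LAS, while 3 fell with each (with an estimated correlation the adjusted p = 0.224, 0.424, 0.387, 0.417 and 0.516). E2+4OHT held LINC01588 at 9.19 against 3.93 with E2 (5.25 ± 0.17), KRT13 at 7.31 against 2.47 (4.83 ± 0.20), TEX14 at 6.78 against 3.13 (3.65 ± 0.15) and CLIC3 at 10.96 against 7.50 (3.46 ± 0.10). With E2 alone LINC01588, KRT13 and TEX14 stood below 4, so their differences may be lower bounds. Against E2 alone 3692 genes were higher and 3098 lower with 4OHT, 4350 and 3499 with ICI, 4409 and 3325 with BZA, 4278 and 3344 with RAL, and 3468 and 2855 with LAS.

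The comparison of each ligand with and without E2 shows what E2 still does while the ligand is present. With 4OHT present, E2 raised TEX14 (2.90 ± 0.15, adjusted p = 1.16e-30), RAMP3 (2.58 ± 0.17), the growth factor binding protein gene IGFBP4 (2.12 ± 0.13), GREB1 (2.05 ± 0.14) and PGR (1.52 ± 0.15), and lowered IL1R1 (-1.15 ± 0.14), AHRR (-0.94 ± 0.24), CSTA (-0.77 ± 0.10) and FTX (-0.76 ± 0.12). The other probe set of GREB1, at 0.21, was not called. It raised 34 of 42 estrogen-induced genes and lowered none (adjusted p = 3.14e-28, and adjusted p = 0.00132 with an estimated correlation). It raised 33 of 36 G1/S genes (adjusted p = 1.04e-34, and adjusted p = 0.0228 with an estimated correlation) and 30 of 33 mitotic genes (adjusted p = 4.32e-13, and adjusted p = 0.418 with an estimated correlation). In all, 1426 genes rose and 1025 fell. Of the 567 genes that E2 alone raised at least 2-fold, 485 were higher here, against 78.4 under independence.

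With ICI present, E2 raised MYBL1 (1.25 ± 0.22), SOX3 (1.21 ± 0.11), MGP (0.94 ± 0.16) and RASGRP1 (0.91 ± 0.23) and lowered PPFIBP2 (-0.73 ± 0.13), while the other probe set of MYBL1, at 0.15, was not called. Both means of MYBL1 in this comparison lay below 4, so its rise may lie within the background. It raised 22 of 42 estrogen-induced genes, and 30 adjusted over the list alone (adjusted p = 6.13e-32, and adjusted p = 0.000647 with an estimated correlation). With BZA present it raised RBM24 (0.82 ± 0.17), IGFBP4 (0.61 ± 0.13), the carbonic anhydrase gene CA2 (0.49 ± 0.09) and PCP4 (0.40 ± 0.09), and 3 of 42 estrogen-induced genes, or 13 adjusted over the list alone (adjusted p = 2.97e-14, and adjusted p = 0.0415 with an estimated correlation). With RAL present it raised GREB1 (0.79 ± 0.14), CXCL12 (0.78 ± 0.15), RBM24 (0.68 ± 0.17) and IGFBP4 (0.66 ± 0.13), although the other probe sets of GREB1 (0.00) and CXCL12 (0.17) were not called, and 7 of 42 estrogen-induced genes, or 23 adjusted over the list alone (adjusted p = 4.89e-22, and adjusted p = 0.00592 with an estimated correlation). Of 36 G1/S genes 6 rose with ICI present and none with BZA or RAL, and adjusted over the list alone 21, 8 and 17 rose (adjusted p = 4.25e-13, 5.44e-10 and 1.76e-14, and adjusted p = 0.274, 0.403 and 0.239 with an estimated correlation). The called genes numbered 180 up and 98 down with ICI, 9 and 3 with BZA, and 28 and 20 with RAL. With the numbering set as a block they numbered 1030, 240 and 485 in all.

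With LAS present, limma called 0 genes for E2. Of the 10307 tested genes 850 had an unadjusted p under 0.05, a number that includes those that pass without any effect. Of simulated genes changed 1.2-fold, 3 arrays against 3 recovered only 34%, and recovery may be lower where few genes change more. With the set as a block 1.22% of the tested genes were called, and with no filter on low values 176 genes. With the LAS and E2+LAS arrays paired by their order 0 genes were called, and 175 with these pairs and the sets as terms (alternatives chosen after the data were seen). Leaving out LAS replicate 1, LAS replicate 3 or E2+LAS replicate 1 gave 4, 1 and 3 genes. GREB1 stood at 1.12 ± 0.26 (adjusted p = 0.182). Adjusted over the list alone, E2 raised 2 of 42 estrogen-induced genes and 4 of 36 G1/S genes. The estrogen-induced list stood higher as a whole (median 0.23, adjusted p = 2.32e-10, and adjusted p = 0.113 with an estimated correlation).

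The share of the E2 response left was taken as the slope of the E2 effect with a ligand on the E2 effect without it, over the 968 genes that E2 moved at least 2-fold. It was 27.8% with 4OHT (95% interval 22.2 to 33.6), 11% with ICI (5.05 to 16.8), 7.81% with BZA (2.67 to 13.0), 8.53% with RAL (3.38 to 13.5) and 12.5% with LAS (10.2 to 14.8). The LAS interval comes from resampling 3 arrays per group, which gives few distinct resamples. 4OHT left more than each other ligand, by 15.4 points over LAS (9.44 to 21) to 20 points over BZA (12.7 to 27.9). The other 6 pairs had intervals over these 968 genes that included 0, for example -0.724 points for BZA minus RAL (-7.95 to 6.65). The resampling left out the numbering sets, whose arrays deviate together. An interval that includes 0 therefore does not show that 2 ligands left the same share. Over the estrogen-induced list the share left was 35.4% with 4OHT (29.4 to 42.0), 18.2% with ICI (13.95 to 22.2), 9.96% with BZA (6.58 to 13.1), 13.6% with RAL (9.34 to 17.8) and 16.1% with LAS (5.47 to 26.2). Differences between ligands over this list were not tested, but the ICI and BZA intervals did not overlap. The share given by each ligand alone was 2.92% with 4OHT (-6.34 to 10.7), -35.6% with ICI (-46.7 to -25.5), -23.3% with BZA (-33.7 to -13.8), -17.3% with RAL (-27.2 to -8.08) and -7.12% with LAS (-15.8 to 0.746), where a negative share means that these genes together moved away from the E2 level. Among the 401 genes that E2 lowered only ICI gave a share whose interval excluded 0, at -21.6% (-29.9 to -14.2), against -6.76% with BZA (-14.3 to 0.314), -1.60% with RAL (-8.86 to 4.74) and 4.12% with LAS (-2.96 to 10.5). Over the 968 genes with another division of the vehicle arrays the LAS share was -6.15% (-11.9 to -0.820), and over the estrogen-induced list it was -7.79% (-15.7 to -0.657), which exclude 0. Among the 567 genes that E2 raised the share was -42.4% with ICI, -31.3% with BZA, -24.9% with RAL and -12.6% with LAS (-23.5 to -2.74). For the share over all 968 genes the intervals of all 10 pairs of ligands excluded 0, the nearest being BZA minus RAL at -5.98 points (-10.8 to -0.869). These shares pool the 2 parts of the arrays by array median. The estrogen-induced score minus vehicle differed between the parts with 4OHT, ICI, BZA and RAL, in the comparison of parts given below.

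**Figure D2:**
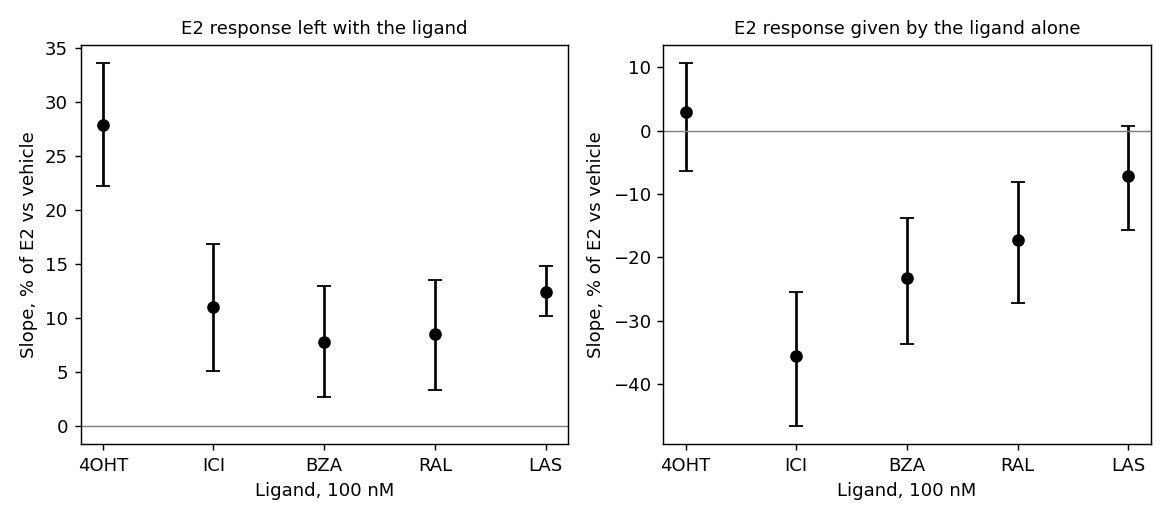
Share of the E2 response in percent (axis) left with each ligand in the presence of E2 and given by each ligand alone, with 95% bootstrap intervals (bars). 4OHT left 27.8%, and ICI alone gave -35.6%.

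The interaction tests whether the E2 effect differed with a ligand present. It did so for 5583 genes with 4OHT, 6114 with ICI, 6298 with BZA, 6236 with RAL and 4565 with LAS. The largest reductions were those of EGR3 (-4.24 ± 0.19 with 4OHT and -4.75 ± 0.19 with ICI) and of GINS4 or MYBL1, and the fall of AHRR was smaller by 3.37 ± 0.34 with 4OHT and 3.90 ± 0.34 with BZA. An additive difference between runs cancels in the interaction with LAS.

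The 5 ligands were compared at the same dose and time. 4OHT is a triphenylethylene, RAL a benzothiophene, BZA an indole, LAS a tetrahydronaphthalene and ICI a steroid derived from estradiol. 4OHT and ICI differed most widely: LINC01588 was higher with 4OHT by 5.24 ± 0.17 and AGR2 by 3.83 ± 0.11 (11.33 against 7.49), and RFTN1 and ATP2C2 were lower by 2.47 ± 0.11 and 2.09 ± 0.11. In all, 3542 genes differed. KRT13 was higher with 4OHT by 3.54 ± 0.20 against BZA, 3.54 ± 0.20 against RAL and 3.49 ± 0.30 against LAS. KRT13 and LINC01588 stood near the background with the other ligands, so these differences may be lower bounds. 4OHT differed from BZA in 2098 genes, from RAL in 1220 and from LAS in 254. The last count rests on 3 LAS arrays, which recover fewer small changes. ICI differed from BZA in 754 genes, with GREB1 higher by 1.61 ± 0.14 (0.01 and not called with its other probe set) and the amino acid transporter gene SLC6A14 lower by 2.14 ± 0.10, from RAL in 1476, with the calcitonin receptor gene CALCR lower by 2.47 ± 0.15, and from LAS in 1432. BZA and RAL differed in 44 genes: AGR2 stood at 8.61 with BZA and 9.59 with RAL (-0.97 ± 0.11, adjusted p = 2.24e-10), CALCR was lower with BZA by 0.83 ± 0.15, and ATP2C2 and TGFA were higher with BZA by 0.45 ± 0.11 and 0.44 ± 0.11. The other probe set of CALCR was called neither here nor for ICI against RAL (-0.11 and -0.18), nor was that of ATP2C2 called between BZA and RAL (0.21). With the set as a block the counts were 3198 for 4OHT against BZA, 2163 for 4OHT against RAL, 1703 for ICI against BZA, 2521 for ICI against RAL and 199 for BZA against RAL.

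LAS differed from RAL in 61 genes and from BZA in 221. AGR2 was lower with RAL than with LAS by 0.93 ± 0.16 and CA2 by 0.84 ± 0.13, and RFTN1 and FAM118A were higher by 0.68 ± 0.16 and 0.66 ± 0.15. The count against RAL was 6 without LAS replicate 2, 160 without the 3 arrays that correlated least with their group (an alternative chosen after the data were seen), 8 with the compared groups alone and 4 with the set as a block. That block took the arrays of both lasofoxifene groups as the same set. The count against BZA was 94 without LAS replicate 2 and 146 without LAS replicate 1, and that against 4OHT was 67 without LAS replicate 2. Without LAS replicate 1, 1.34% of the tested genes differed between 4OHT and LAS in place of 2.46%. These contrasts may also be contrasts between runs.

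With E2 present 4OHT again stood apart: LINC01588 was higher than with E2+ICI by 6.69 ± 0.17 and KRT13 by 4.86 ± 0.20, and 5044 genes differed. LINC01588 and KRT13 stood near the background with E2+ICI, so their differences may be lower bounds. E2+4OHT differed from E2+BZA in 4360 genes, from E2+RAL in 3504 and from E2+LAS in 832, where 3 arrays again recover fewer small changes. E2+ICI differed from E2+BZA in 545 genes, from E2+RAL in 1054 and from E2+LAS in 1298, with AGR2 lower by 1.44 ± 0.11, 2.41 ± 0.11 and 3.21 ± 0.16. E2+BZA and E2+RAL differed in 55 genes, again with AGR2 (-0.96 ± 0.11) and CALCR (-0.87 ± 0.15, and -0.31 and not called with its other probe set) lower with BZA. E2+LAS differed from E2+BZA in 553 genes, with CSTA and DRD1 lower with LAS by 0.96 ± 0.15 and 0.95 ± 0.20, and from E2+RAL in 9, with SDK2 and the prostaglandin synthase gene PTGES higher with LAS by 1.14 ± 0.17 and 1.06 ± 0.20 (the other probe set of PTGES, at 0.39, was not called). Without E2+LAS replicate 1 the count was 159 against E2+BZA and 3 against E2+RAL, and without E2+LAS replicate 3 it was 433 against E2+4OHT, 180 against E2+BZA and 804 against E2+ICI. Against E2+ICI it was 836 without E2+LAS replicate 1 and 798 with the set as a block. Without E2+LAS replicate 2 it was 2 against E2+RAL. With the set as a block the counts were 1652 for E2+ICI against E2+BZA, 1935 for E2+ICI against E2+RAL and 241 for E2+BZA against E2+RAL.

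Mean scores of 7 fixed lists were compared between ligands by 2-sided permutation tests, and 76 of 140 had an adjusted p under 0.05. The estrogen-induced score was 8.17 ± 0.12 with 4OHT (SD, n = 10), 7.87 ± 0.09 with LAS (SD, n = 3), 7.66 ± 0.08 with RAL, 7.47 ± 0.07 with BZA and 7.13 ± 0.05 with ICI, against 7.88 ± 0.18 with vehicle. All 10 pairs differed, from 4OHT minus ICI at 1.043 (95% interval 0.94 to 1.147, permutation p = 3e-05) to BZA minus RAL at -0.194 (-0.298 to -0.091, permutation p = 8e-05). RAL minus LAS was -0.207 (-0.359 to -0.054, exact permutation p = 0.00699, the smallest that 10 arrays against 3 can give). With E2 present 9 of 10 pairs differed, and RAL minus LAS was -0.227 (-0.38 to -0.075, exact permutation p = 0.035, adjusted p = 0.0628). The G1/S score of BZA minus RAL was -0.166 alone (-0.354 to 0.023, permutation p = 0.0854, adjusted p = 0.142) and -0.213 with E2 (-0.402 to -0.025, permutation p = 0.0167, adjusted p = 0.0326). It was lower with BZA in 10 of 10 sets in both arms, and sign flips within sets, a test chosen after the data were seen, gave an exact p = 0.00195 in each (adjusted p = 0.00471). The cholesterol synthesis score of BZA minus RAL was 0.009 with E2 (-0.047 to 0.066), and alone the interval ran from -0.056 to 0.057. The unfolded protein response score differed in no pair after adjustment, though it did in 3 pairs when tested within sets. The score of aryl hydrocarbon receptor targets differed in 4OHT minus ICI with E2 (-0.167, adjusted p = 0.0308), and within sets in 7 further pairs, for example ICI minus BZA alone (0.105, higher in 10 of 10 sets, exact p = 0.00195, adjusted p = 0.00471).

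The scores minus vehicle were also compared between sets 1 to 6 and sets 7 to 10, the 2 parts of the arrays by array median, after the data were seen. For E2, 4OHT, ICI, BZA and RAL, which share the vehicle arrays, 17 of 35 differed at an adjusted p under 0.05. E2 raised the G1/S score by 1.635 in the first part and 2.281 in the second (exact permutation p = 0.00476, adjusted p = 0.0208), and ICI lowered the estrogen-induced score by 0.848 and 0.598 (exact permutation p = 0.00476, adjusted p = 0.0208). Other differences changed sign. The estrogen-repressed score minus vehicle was 0.103 and -0.076 with RAL and 0.062 and -0.078 with 4OHT (exact permutation p = 0.00476, adjusted p = 0.0208 for each). With RAL the estrogen-induced score minus vehicle was -0.311 and -0.076 (exact permutation p = 0.0143, adjusted p = 0.0455). The estrogen-induced score of the vehicle arrays themselves was 8.003 and 7.692 (exact permutation p = 0.00952). That of E2 was 9.532 and 9.31 (exact permutation p = 0.019). With 4OHT, ICI, BZA and RAL it did not differ at 0.05 (exact permutation p = 0.31, 0.0667, 0.0571 and 0.143). A shift of the shared vehicle arrays may thus give many of the 17 differences, which are not separate results.

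**Figure D3:**
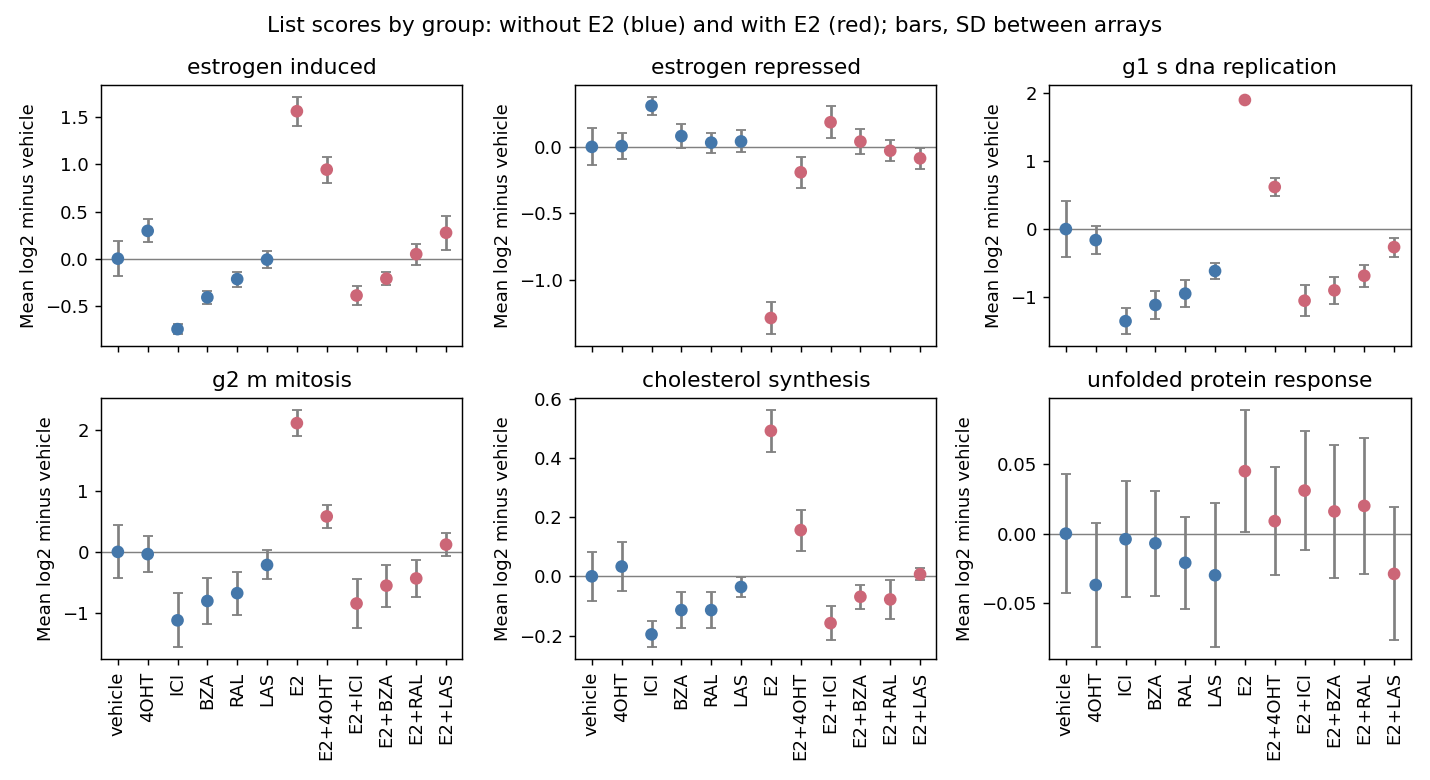
Mean log2 score of 6 fixed gene lists minus vehicle (y axis) in each group (x axis), with SD bars over arrays. The estrogen-induced score lies 1.565 above vehicle with E2 and 0.748 below it with ICI.

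The difference between the 3-prime and 5-prime control probe sets of GAPDH, a measure of RNA integrity, lay between a mean of 0.313 with E2+RAL and 0.366 with E2 (permutation p = 0.0185, adjusted p = 0.0278), and that of beta-actin differed between numbering sets (permutation p = 3e-05). The first principal component held 60.6% of the variance and followed the groups, and the fourth held 3.1% and followed the numbering sets.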

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

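The test of the numbering sets as terms, the 3 lower bounds of the share left, the E2 effect on the genes that 4OHT raised, the fit with the parts by array median, the splits within numbering sets, the numbering sets held out, the comparison of the parts by array median, the comparison of SDs between vehicle and ICI arrays and the upper bound of the share given by ICI were chosen only after the results were seen.

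Single arrays lay far from the others of their group in 6 of 270 tested sets of values, where chance gives about 13.5. ESR1 was lowest in E2+4OHT replicate 3 (11.611), GREB1 in vehicle replicate 10 (9.296) and in E2 replicate 8 (11.323), CXCL12 in 4OHT replicate 5 (5.367) and SQLE in E2 replicate 2 (10.828), and ERBB2 was highest in RAL replicate 5 (8.702).

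The E2 effect differed with the ligand for 5583 genes with 4OHT, 6114 with ICI, 6298 with BZA, 6236 with RAL and 4565 with LAS. It was called in opposite directions without and with 4OHT for 27 genes, of which 24 fell with E2 alone and rose with E2 beside 4OHT. IGFBP3, a growth factor binding protein gene, fell by 1.16 on the log2 scale with E2 alone and rose by 0.74 beside 4OHT (interaction 1.90 ± 0.17, adjusted p = 5.85e-18). With E2 alone IGFBP3 lay below 4 on each array and may stand at the background, so that fall may be a lower bound. With ICI there were 9 such genes, among them SOCS3 (-0.67 and 0.56, interaction 1.24 ± 0.22, adjusted p = 6.48e-07).

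Probe sets without exactly 1 gene name stood outside the gene counts. Of 3382 of them above the floor, 2179 were called for E2 against vehicle, 738 up and 1441 down, and 274 at least 2-fold.

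Few genes were called for E2 in the presence of BZA, RAL or ICI, 338 in the 3 contrasts together. Variation between numbering sets may hide small effects, since 1755 genes were called with the sets as terms. That no E2 response is left was excluded over the 968 genes together by the intervals of the share left, whose lowest lower bound was 2.67%. Among the 401 genes that E2 lowered the interval lay above 0 with ICI and RAL, but the lowest lower bound, that of RAL, was only 0.254%. With BZA the interval ran from -0.0341% to 9.54% and included 0. The bounds of RAL and BZA lie close to 0 and to each other. For these genes the question therefore stays open with both RAL and BZA.

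Genes that 4OHT alone raised at least 2-fold numbered 50, of which E2 raised 39 and lowered 6 against the same vehicle arrays, where independence gives 17.1 rises. A simulated unchanged group gave a mean of 0.01. Its noise was independent between genes and held no set effects, so it is no benchmark for these arrays. With the vehicle arrays divided between both comparisons E2 raised 38 and lowered 7 of 53 in either division. Background correction near the floor could not account for all of them, as 23 had a vehicle mean of at least 6, while 16 had one under 4. Chance or handling of the 4OHT and vehicle arrays is not a likely source, because 40 of the 50 were also higher in E2+4OHT than in E2, which shares no arrays with the first comparison, against 17.9 under independence. The rise did not rest on a few numbering sets, since with genes chosen without a set their median in that set was above 0 in 10 of 10 sets (1.09 to 1.64).

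LAS and RAL differed in 61 genes. A run effect of the lasofoxifene arrays may have contributed: the differences from RAL without and with E2, which share no arrays, correlated at r = 0.503 across genes. With the 2 parts of the arrays by array median as a term, which the lasofoxifene arrays share with the other groups, 78 genes were called. An effect of the ligand and an effect of a separate run would both give the correlation, and they cannot be told apart.

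Chance assignment of the arrays was tested with up to 100 splits that mix the arrays of the compared groups, counting the real one. No other split reached the real count, a value of 1, for E2 against vehicle (7471, highest other 5850), 4OHT (1266 and 682), ICI (2723 and 1806) and BZA (1454 and 1262) against vehicle, nor for the comparisons with E2 alone of 4OHT (6790 and 5014), ICI (7849 and 6504), BZA (7734 and 6174), RAL (7622 and 6207) and LAS (6323 and 4022). The same held for E2 in the presence of 4OHT (2451 and 338), ICI (278 and 58) and RAL (48 and 2), and for the interactions with 4OHT (5583 and 3694), ICI (6114 and 5227), BZA (6298 and 4167) and RAL (6236 and 4950). Among pairs it held for 4OHT against ICI (3542 and 1308), BZA (2098 and 1601), RAL (1220 and 401) and LAS (254 and 39), ICI against BZA (754 and 103), RAL (1476 and 371) and LAS (1432 and 414), and BZA against LAS (221 and 34). With E2 it held for 4OHT against ICI (5044 and 2864), BZA (4360 and 2108), RAL (3504 and 796) and LAS (832 and 39), ICI against BZA (5.29% and 1.19% of the tested genes), RAL (1054 and 197) and LAS (1298 and 277), BZA against RAL (55 and 5) and RAL against LAS (9 and 3). Splits of an interaction mix the arrays of all its groups, so the E2 effect itself enters each split. They therefore cannot tell whether chance gave an interaction. For the other comparisons chance is an unlikely source, but shares of 1 in 100 splits were not corrected for the 41 comparisons. E2+RAL against E2+LAS rests on few genes, and with the set as a block 4 were called.

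In 2 splits, counting the real one, at least the real count was called for RAL against vehicle (1760, highest other 2127), LAS against vehicle (643 and 1020), BZA against RAL (44 and 263), E2+BZA against E2+LAS (553 and 748) and the gene lists (216 and 219), and in 3 for E2 in the presence of BZA (12 and 237) and the interaction with LAS (4565 and 5604). Each share lies under 0.05, again without a correction for the number of comparisons. Apart from the interaction with LAS, chance is a more likely source for these than for the comparisons above. For that interaction the splits cannot tell, as they mix all its groups. With arrays swapped only within numbering sets, and the sets as terms, no other of 100 splits reached the real count for RAL against vehicle (2736 and 2253), BZA against RAL (199 and 88) and E2 in the presence of BZA (240 and 66). For RAL against LAS 6 splits did so (61 and 1447), and chance was not excluded. Splits that call several times the real count, as for RAL against LAS, BZA against RAL and E2 in the presence of BZA, point to a structure of the samples. For E2 in the presence of LAS limma called 0 genes, and 850 of 10307 had an unadjusted p under 0.05. The highest other count was 0, all 10 splits reached it, and 10 splits are too few for a share under 0.05.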

How the results depend on the processing

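The leaving out of the 3 arrays that correlate least with their group, the random block, the leave-outs of lasofoxifene arrays in list scores and shares, the parts by array median as a term, the pairs of lasofoxifene arrays and the list scores within sets were chosen only after the results were seen. The title numbers do not pair the arrays strictly: the median correlation of deviations between arrays of the same set was 0.373, but 24 of 450 such pairs lay at or under 0.1, the lowest at -0.0713. Against arrays of other sets the median was -0.0359, and 97 of 100 arrays correlated best with an array of their own set. The consensus correlation within sets was 0.297, with the arrays of both lasofoxifene groups taken as the same set. The block leaves the log2 differences as they are and changes their error, so a call lost under it is not a smaller difference. Of 9876 values of named genes under alternatives 9593 stayed on the same side of the threshold, 160 were no longer called, 77 were newly called and 46 changed sign. Of 620 counts 504 stayed within 1.5 times, and of 620 counts of at least 2-fold 574 did. The 3 arrays per lasofoxifene group and the missing detection calls limit small and low values most. Without each lasofoxifene array in turn the share left ran from 11.48% to 13.35% and the share given from -8.02% to -6.529%. With the LAS and E2+LAS arrays paired by order as a replicate block 0% of the tested genes were called for E2+LAS vs LAS. With list scores compared within sets 95 of 140 were called, all 76 of the unpaired tests and 19 more, for example G2/M and mitosis for ICI minus BZA (-0.316, lower in 10 of 10 sets, exact p = 0.00195, adjusted p = 0.00471). The cause was not tested for any changed result below.

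Numbers of called genes are given here as percent of the features tested under the same setting, while whether a number stayed within 1.5 times was decided on the counts themselves. With array weights, the share of tested features called was 0.262% for E2+BZA vs BZA, 1.98% for E2+RAL vs RAL, 12.9% for E2+4OHT vs E2+LAS, 8.12% for E2+BZA vs E2+LAS and 0.359% for E2+RAL vs E2+LAS. With an estimated correlation, 48 of the 738 list tests were called. Over the fixed list of estrogen-induced genes, the share left was 35.43% with 4OHT, 18.22% with ICI, 13.56% with RAL and 16.14% with LAS. With every probe set counted on its own, which tests more features, the share of tested features called was 69.8% for E2 vs vehicle, 5.49% for LAS vs vehicle, 61% for E2+4OHT vs E2, 73.1% for E2+ICI vs E2, 71.6% for E2+BZA vs E2, 70.6% for E2+RAL vs E2, 56.7% for E2+LAS vs E2, 22.4% for E2+4OHT vs 4OHT, 0.516% for E2+RAL vs RAL, 48.7% for interaction E2 x 4OHT, 54.4% for interaction E2 x ICI, 56.3% for interaction E2 x BZA, 55.7% for interaction E2 x RAL, 38.8% for interaction E2 x LAS, 29.5% for 4OHT vs ICI, 2.18% for 4OHT vs LAS, 11.7% for ICI vs LAS, 0.516% for RAL vs LAS, 44.8% for E2+4OHT vs E2+ICI, 37.8% for E2+4OHT vs E2+BZA, 29.7% for E2+4OHT vs E2+RAL, 6.8% for E2+4OHT vs E2+LAS and 0.0914% for E2+RAL vs E2+LAS. With the mean of all probe sets of a gene, the share of tested features called was 0.16% for E2+RAL vs E2+LAS. With no filter on low values, the share of tested features called was 5.21% for LAS vs vehicle, 0.0152% for E2+BZA vs BZA, 0.89% for E2+LAS vs LAS, 3.04% for 4OHT vs LAS, 2.96% for BZA vs LAS, 2.21% for RAL vs LAS and 0.501% for E2+RAL vs E2+LAS. With the arrays of the compared groups alone, which leaves fewer arrays for the spread, the share of tested features called was 9% for BZA vs vehicle, 9.38% for RAL vs vehicle, 1.47% for LAS vs vehicle, 0.194% for E2+RAL vs RAL, 1.25% for 4OHT vs LAS, 1.18% for BZA vs LAS, 0.0776% for RAL vs LAS, 2.77% for E2+BZA vs E2+LAS and 0.155% for E2+RAL vs E2+LAS. With the numbering set as a replicate block, the share of tested features called was 20.7% for 4OHT vs vehicle, 23.5% for BZA vs vehicle, 26.5% for RAL vs vehicle, 2.84% for LAS vs vehicle, 9.99% for E2+ICI vs ICI, 2.33% for E2+BZA vs BZA, 4.71% for E2+RAL vs RAL, 1.22% for E2+LAS vs LAS, 31% for 4OHT vs BZA, 21% for 4OHT vs RAL, 0.669% for 4OHT vs LAS, 16.5% for ICI vs BZA, 24.5% for ICI vs RAL, 8.89% for ICI vs LAS, 1.93% for BZA vs RAL, 0.961% for BZA vs LAS, 0.0388% for RAL vs LAS, 4.65% for E2+4OHT vs E2+LAS, 16% for E2+ICI vs E2+BZA, 18.8% for E2+ICI vs E2+RAL, 7.74% for E2+ICI vs E2+LAS, 2.34% for E2+BZA vs E2+RAL, 1.74% for E2+BZA vs E2+LAS and 0.0388% for E2+RAL vs E2+LAS. With the numbering set as a random block in every contrast, the share of tested features called was 20.2% for 4OHT vs vehicle, 22.9% for BZA vs vehicle, 26.1% for RAL vs vehicle, 8.99% for E2+ICI vs ICI, 2.04% for E2+BZA vs BZA, 3.89% for E2+RAL vs RAL, 0.728% for E2+LAS vs LAS, 20.4% for 4OHT vs RAL, 15.5% for ICI vs BZA, 23.8% for ICI vs RAL, 1.59% for BZA vs RAL, 15.1% for E2+ICI vs E2+BZA, 18% for E2+ICI vs E2+RAL and 1.96% for E2+BZA vs E2+RAL. Without the 3 arrays that correlate least with their group, the share of tested features called was 0.766% for E2+RAL vs RAL and 1.55% for RAL vs LAS. Without the 6 arrays with the file label suffix, the share of tested features called was 0.0679% for E2+BZA vs BZA. With the 2 parts of the arrays by array median as a term, the share of tested features called was 0.184% for E2+BZA vs BZA and 0.786% for E2+RAL vs RAL. With the numbering set and the order of the lasofoxifene arrays as a replicate block, the share of tested features called was 1.7% for E2+LAS vs LAS. Leaving out each lasofoxifene array in turn gave 3.68 to 4.4% for LAS vs vehicle, 0 to 0.0388% for E2+LAS vs LAS, 0.65 to 2.44% for 4OHT vs LAS, 0.912 to 1.79% for BZA vs LAS, 0.0582 to 0.825% for RAL vs LAS, 4.2 to 5.6% for E2+4OHT vs E2+LAS, 7.8 to 8.97% for E2+ICI vs E2+LAS, 1.54 to 3.69% for E2+BZA vs E2+LAS and 0.0194 to 0.0679% for E2+RAL vs E2+LAS.

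No log2 difference was called with all arrays or under the setting that changed its sign. ESR1 in E2+LAS vs E2 was called without E2+LAS replicate 2 (-0.238, adjusted p = 0.0237), where its sign was that with all arrays. With array weights it was 0.016 for CCNB1 in 4OHT vs vehicle, -0.009 for MYC in E2+BZA vs BZA, 0.028 for ERBB2 in E2+RAL vs RAL, -0.026 for HMGCS1 in E2+RAL vs RAL, -0.038 for INSIG1 in E2+RAL vs RAL, 0.046 for ESR1 in E2+LAS vs LAS, 0.017 for MYC in E2+LAS vs LAS and 0.017 for CYP1B1 in E2+LAS vs LAS. With the mean of all probe sets of a gene it was -0.029 for PGR in 4OHT vs vehicle, -0.006 for CYP1B1 in ICI vs vehicle, 0.029 for HMGCS1 in BZA vs vehicle, 0.023 for BCL2 in RAL vs vehicle, -0.028 for ESR1 in E2+RAL vs E2, 0.098 for CYP1B1 in E2+ICI vs ICI, -0.016 for ESR1 in E2+BZA vs BZA, -0.005 for BCL2 in E2+BZA vs BZA, -0.066 for HMGCS1 in E2+BZA vs BZA, -0.028 for HMGCS1 in E2+RAL vs RAL, 0.022 for ESR1 in E2+LAS vs LAS, 0.064 for CYP1B1 in E2+LAS vs LAS and -0.014 for HMGCS1 in E2+LAS vs LAS. With quantile normalization it was 0 for ESR1 in E2+RAL vs RAL and 0.001 for CYP1B1 in E2+LAS vs LAS. Without the 3 arrays that correlate least with their group it was -0.132 for PGR in 4OHT vs vehicle, -0.065 for PDZK1 in 4OHT vs vehicle, -0.011 for HMGCS1 in 4OHT vs vehicle, -0.041 for MKI67 in 4OHT vs vehicle, -0.018 for HMGCS1 in LAS vs vehicle, 0.043 for ERBB2 in E2+RAL vs RAL, -0.014 for HMGCS1 in E2+RAL vs RAL and -0.037 for INSIG1 in E2+RAL vs RAL. Without the 6 arrays with the file label suffix it was -0.002 for INSIG1 in E2+ICI vs ICI. Leaving out each lasofoxifene array in turn, it ran from -0.289 to 0.03 for CCNB1 in LAS vs vehicle, -0.182 to 0.084 for ESR1 in E2+LAS vs LAS, -0.096 to 0.346 for TFF1 in E2+LAS vs LAS, -0.088 to 0.043 for MYC in E2+LAS vs LAS, -0.122 to 0.076 for CCNG2 in E2+LAS vs LAS, -0.115 to 0.058 for CYP1B1 in E2+LAS vs LAS and -0.238 to 0.027 for ESR1 in E2+LAS vs E2.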

Other observations

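Further named genes changed with E2 in these cells. Of the immediate early genes JUNB fell by 1.13 ± 0.10, and of the luminal genes ELF3 fell by 1.40 ± 0.08 and FOXA1, a pioneer factor for the estrogen receptor, by 0.90 ± 0.08. CYP1B1, which encodes an enzyme of estradiol hydroxylation, rose by 0.79 ± 0.07.

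The estrogen-induced score varied more between vehicle arrays (SD 0.183) than between ICI arrays (SD 0.0527, 2-sided permutation p = 0.00023). It also varied with E2 (SD 0.153), E2+4OHT (SD 0.139) and 4OHT (SD 0.122), so the spread was not confined to vehicle. The vehicle score followed the 2 parts of the arrays by array median, with 7.811 to 8.096 in sets 1 to 6 and 7.635 to 7.775 in sets 7 to 10 (exact permutation p = 0.00952), and the E2 score differed between them too (exact permutation p = 0.019). A difference between the parts may account for much of the spread, and a varying residual estrogen activity in the medium could be part of it or act beside it. The data cannot tell what differed between the parts, and ICI treatment of cells in medium of measured estradiol content would test the second.

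ICI, BZA and RAL alone lowered genes that E2 raised, and the upper bound of the share given by ICI was -25.5%. Residual estrogen activity in the vehicle medium may account for this, and so may an activity of the receptor without a ligand. The data cannot tell, and a vehicle series with added estradiol well under 1 nM would test the first.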
